A study of Mus musculus with 13 samples.

How the data were processed

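Poly(A)-selected RNA from the hippocampus of 5xFAD mice, which carry human transgenes with familial Alzheimer's disease mutations, was sequenced in bulk. The 13 libraries fall into 3 treatment groups, and the labels number the animals. Saline has 4 libraries (18, 19, 32 and 38), Aducanumab, an antibody to aggregated amyloid beta, has 4 (24, 50, 56 and 58), and ACLP-NT, known here only by its code name, has 5 (17, 27, 49, 53 and 55). No batch, date, dose or treatment time is given in the sources used here, and no replicate number occurs in more than 1 group.

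The deposited table lists 36287 genes with FPKM and raw counts for every library. Per the file headers, FPKM values are fragment counts scaled by the authors to gene length and to library total. Counts are whole numbers, deposited by the authors without normalization. The submitters' notes name cutadapt 1.9, HISAT2 2.0.4, StringTie 1.3.4d and edgeR without a version. The counter, the annotation release and the genome build are not given in the sources used here. Of 33727 gene identifiers shared with a GRCm38 annotation, 655 had equal start and end positions, so coordinates are given as the table prints them and were not mixed with another annotation. Both kinds of column were checked against each other. Over 15196 genes with over 50 counts in every library, the gene length implied by count and FPKM varied between libraries by a median ratio of 1.01, and 99.9% of these genes had a ratio under 1.05. In 55 cases an FPKM of 0 stood beside a count above 0.

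Total counts ran from 53642019 (ACLP-NT 53) to 69734713 (saline 38), and 26434 to 27598 genes had a count above 0 in a library. No pair of libraries within a group agreed within counting error (chi-square per degree of freedom at least 14.0), so each counts as 1 sample. Of the 22065 genes tested, 7013 (31.8%) had a mean count under 100, where counting error alone exceeds 10% in 1 library. The p-values measure spread between these samples alone.

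The comparisons, the 35 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The plan provided for a test on FPKM and for a test on raw counts if these were present. As they were, the counts were used. Genes were filtered with filterByExpr (22065 tested), scaled by TMM and compared with the edgeR 4.0.16 quasi-likelihood test (glmQLFit, glmQLFTest, two-sided) with the 3 groups in 1 fit, Benjamini-Hochberg adjusted with a threshold of 0.05. The common biological coefficient of variation was 0.226. Levels are CPM as edgeR gives them after TMM, and fold changes are on the log2 scale. The standard error (SE) of an edgeR fold change was derived from the quasi-likelihood test. It is the absolute log2 fold change divided by the square root of the F statistic.

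Gene lists covered lysosome and autophagy, microglial and astrocyte states, immune responses, neurons and synapses, lipid and energy metabolism, amyloid processing, and markers of other cell types and of neighbouring tissue. Of 35 lists, 34 had at least 5 tested members, and the sex-linked list was left out. Each was tested with camera (limma 3.58.1, preset correlation 0.01, two-sided, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. A score per library, the mean centred log2 CPM of the members (prior count 2), was compared by exact two-sided permutation tests, which were chosen after seeing the data. Members were also adjusted over the list alone. Of the 11 blood cell markers, 5 were tested: the hemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, and Alas2. As S100a8, S100a9, Ngp, Camp, Ly6g and Retnlg were left out, that list covers hemoglobin genes and Alas2 alone.

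Where fewer than 5 genes passed, the rule named the 10 genes with the smallest unadjusted p, leaving out pseudogenes and predicted genes. It also named the 3 members with the smallest p of each list called, and a fixed set of genes in every comparison, among them App, Trem2, Cst7, Clec7a, P2ry12, Gfap, Ctsd, Lamp1 and Tfeb. Some genes that the rule names are left out of the text.

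The method was tested on simulated data made from these counts. In ACLP-NT against saline, edgeR recovered 7.46% of 67 genes changed 1.25-fold, 50.7% of 67 changed 1.5-fold and 62.1% of 66 changed 2-fold, with 0 false among 82 calls, 2 of them members of the list shifted in the same simulation. In Aducanumab against saline the recovered shares were 13.4%, 34.3% and 53.0%, with 1 false among 68 calls. A list shifted by -0.20 was found by camera in both, and 0 and 1 of 33 other lists were called. Genes were drawn independently of each other here, so a low number of false lists was built in. The simulation therefore says nothing on lists of correlated genes. Over splits of the real libraries, given below, the median was 11 to 13 lists called.

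Alternatives were no filter, a mean FPKM of at least 5, upper quartile and RLE scaling, a robust fit, only the 2 groups compared, each library left out in turn, limma on log2(FPKM + 1) and log2(FPKM + 0.1), quantile normalization, array weights, and DESeq2 1.42.0. Chosen after seeing the data were covariates for choroid plexus and thalamus scores, a fit without 3 libraries (saline 38, Aducanumab 50 and 58), and a camera test of 321 KEGG pathways from the table's own annotation. R 4.3.3, the data.table package (1.17.8), pandas 2.3.3 and matplotlib 3.10.9 were used.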

Results

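Hippocampal mRNA was compared between 5xFAD mice given saline (n = 4), Aducanumab (n = 4) or ACLP-NT (n = 5). Total counts per library were 57513570 to 69734713 in saline, 56858092 to 64431803 in Aducanumab and 53642019 to 64874729 in ACLP-NT. Xist, the transcript of the inactive X chromosome in females, lay between 941 and 1126 CPM in all 13 libraries. No wild-type mice are among the libraries, so saline-treated 5xFAD mice are the background for every value.

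The largest difference between libraries was present within every treatment group. The first principal component held 18.2% of the variance and was led by Ttr, Cdh3 and Kcne2, genes of the choroid plexus, the epithelium that secretes cerebrospinal fluid. Ttr, which encodes transthyretin, ran from 21 CPM in saline 18 to 4556 CPM in Aducanumab 58. Each group held libraries at both ends: the choroid plexus score was 2.14 in saline 38 and -2.83 in saline 18, 2.24 in Aducanumab 58 and -2.65 in Aducanumab 50, and 2.10 in ACLP-NT 53 and -2.72 in ACLP-NT 55. Thalamus and midbrain scores were 1.3 in Aducanumab 50 against -0.19 to -0.030 in the saline libraries. Meningeal fibroblast and blood cell markers were at 1.41 and 1.12 in Aducanumab 58.

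**Figure D1:**
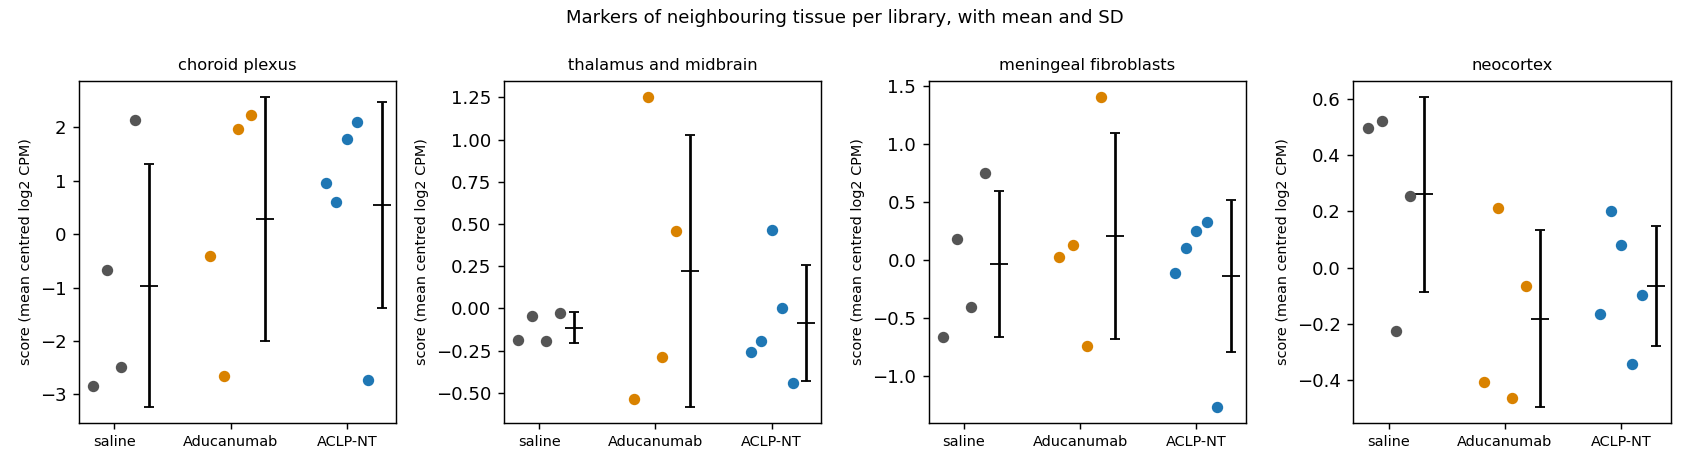
Scores of 4 marker lists for neighbouring tissue (mean centred log2 CPM of the members, vertical axes) per library in the 3 treatment groups, with the group mean and SD. Choroid plexus scores span -2.83 to 2.24, and each group has libraries at both ends.

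ACLP-NT against saline addresses whether the treatment, which the series title places with the lysosomes of microglia, changed hippocampal transcripts. Transcripts of disease-associated microglia, the state microglia take around amyloid plaques, were lower in ACLP-NT: 26 of 27 members lay below saline, with a median log2 fold change of -0.31. Cst7, a cathepsin inhibitor induced in that state, averaged 43.2 ± 8.02 CPM (SD, n = 4) in saline and 26.5 ± 9.56 CPM (SD, n = 5) in ACLP-NT, a log2 fold change of -0.70 (SE 0.261). Trem2, the lipid-sensing receptor that microglia need to enter that state, averaged 88.2 ± 15.5 CPM (SD, n = 4) and 62.1 ± 16.1 CPM (SD, n = 5), and Clec7a, a receptor of the same state, 30.3 ± 3.55 and 19.6 ± 6.06 CPM. Homeostatic microglia transcripts had a median of -0.23 with 14 of 17 members lower, among them the purine receptor P2ry12 with 72.1 ± 8.16 CPM (SD, n = 4) in saline and 59.6 ± 4.34 CPM (SD, n = 5) in ACLP-NT. Lysosomal enzymes and membrane proteins had a median of -0.11 with 41 of 50 members lower, among them Grn, the precursor of lysosomal granulins, with 137 ± 4.87 and 107 ± 13.2 CPM. The lysosomal median was -0.066 without saline 38 and -0.067 without ACLP-NT 27.

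These 3 lists were called by camera with the preset correlation, and none was called once the correlation was estimated. The values were adjusted p = 0.336 with an estimated correlation for disease-associated and for homeostatic microglia and adjusted p = 0.402 with an estimated correlation for the lysosomal list. An exact permutation test of the disease-associated score gave p = 0.0794 for a difference of -0.36 (SE 0.147), where the smallest p it allows is 0.00794. Over all genes 0 members of these lists passed in edgeR. When adjusted over the list alone, 7 homeostatic members passed, all lower (Csf1r, Sall1, P2ry12, P2ry13, Gpr34, Selplg and Cx3cr1), and 0 disease-associated or lysosomal members did. Csf1r, the receptor that microglia need to survive, had a log2 fold change of -0.29 (SE 0.0889). In the same comparison the choroid plexus list, a marker of tissue beside the hippocampus, had a median of 0.73 with all 18 members higher (adjusted p = 0.722 with an estimated correlation). That median was 0.39 without saline 18, 0.36 without saline 32 or ACLP-NT 53 and 2.90 without saline 38. ACLP-NT 27 and 53 had the lowest disease-associated scores (-0.57 and -0.39) of the 13 libraries.

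Other immune lists lay in the same direction. Complement and phagocytic receptors had a median of -0.34 with 18 of 19 members lower, led by C3ar1, Itgam and C1qb, and adjusted p = 0.336 with an estimated correlation. Antigen presentation had a median of -0.34 with 18 of 19 lower and adjusted p = 0.422 with an estimated correlation, and Psmb9, a subunit of the immunoproteasome, passed when adjusted over the list alone (log2 fold change -0.81, SE 0.174) and in DESeq2 over all genes (adjusted p 0.0446). Interferon response members had a median of -0.28 with 28 of 29 lower, including Ifi204, Ifit2 and Gbp2 (adjusted p = 0.722 with an estimated correlation), and the median was -0.17 without saline 38, -0.15 without ACLP-NT 27 and -0.43 without ACLP-NT 49. For inflammatory cytokines and the inflammasome the median was -0.19 (-0.12 without ACLP-NT 27) with 16 of 23 lower and adjusted p = 0.691 with an estimated correlation; Casp4 and Gsdmd had log2 fold changes of -0.61 (SE 0.256) and -0.36 (SE 0.166), and Nfkbia, an inhibitor of NF-kappa-B, 0.29 (SE 0.134). Reactive astrocyte transcripts had a median of -0.29 with 17 of 21 lower and adjusted p = 0.622 with an estimated correlation, and Gfap, the intermediate filament of astrocytes, averaged 1494 ± 284 CPM (SD, n = 4) in saline and 1108 ± 247 CPM (SD, n = 5) in ACLP-NT. H2 and Ifit genes have close paralogs, and how reads shared between paralogs were counted is not given in the sources used here.

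Among the remaining calls, cholesterol synthesis (Fdps, Mvd and Nsdhl) had a median of -0.12 with 19 of 20 lower and adjusted p = 0.691 with an estimated correlation. Ribosomal proteins (including Rpl11 and Rpl19) had a median of -0.043 (-0.024 without saline 38) and adjusted p = 0.727 with an estimated correlation. Heat shock and unfolded protein response genes (Hsph1, Manf and Hspa8) had a median of 0.073 and adjusted p = 0.722 with an estimated correlation, and the median was 0.039 without saline 19, 0.12 without saline 38 and 0.025 without ACLP-NT 49. Markers of hippocampal subfields had a median of 0.18 with 14 of 17 higher, led by Tdo2, Prox1 and Dsp, which mark the dentate gyrus, and adjusted p = 0.176 with an estimated correlation. Neocortex markers (Tbr1, Rspo1 and Tshz2) had a median of -0.27 with all 12 lower and adjusted p = 0.402 with an estimated correlation. Exact permutation of the scores gave p = 0.0238 for hippocampal subfields and p = 0.0159 for cholesterol synthesis, and after adjustment over the 34 lists the smallest value was 0.360. As the smallest p this permutation test allows is 0.00794, 1 list alone could not pass after that adjustment.

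Lists without a call included the proton pump of the lysosome and the genes of amyloid processing. The median log2 fold change was -0.014 for V-ATPase subunits, -0.0052 for autophagy and -0.024 for amyloid processing. For neural and glial markers it was -0.030 for astrocyte markers, 0.011 for synaptic genes, 0.031 for immediate early genes, -0.072 for neurogenesis, -0.035 for oligodendrocytes and myelin, -0.049 for oligodendrocyte precursors and -0.041 for neuronal markers. Metabolic lists had medians of -0.043 for lipid handling, -0.022 for the oxidative stress response, 0.013 for nuclear genes of the mitochondrial respiratory chain and -0.050 for mitochondrially encoded genes. Tissue and cell markers had medians of -0.093 for endothelium and pericytes, -0.12 for meningeal fibroblasts, -0.0996 for blood cells, -0.097 for lymphocytes, -0.12 for the striatum and 0.073 for thalamus and midbrain. Adjusted p ran from 0.0991 to 0.937 over these lists with the preset correlation. For autophagy the test pointed up against a negative median and mean, and for synaptic genes and neurogenesis the mean and median differed in sign. App had a log2 fold change of 0.022 (SE 0.0488), and Tfeb, a transcription factor for lysosomal genes, -0.082 (SE 0.118). Whether reads from the human transgenes were counted under mouse genes such as App is not given in the sources used here. Ctsd, a lysosomal protease, was at -0.33 (SE 0.157), and Lamp1, a lysosomal membrane protein, at -0.12 (SE 0.0723).

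No single gene passed in edgeR: 0 of 22065 genes, with the smallest adjusted p at 0.722. At an unadjusted p below 0.05 there were 1298 genes, 542 higher and 756 lower, where 5% of the genes tested is 1103 and the median over 100 splits of these libraries, the real one included, was 830.5; DESeq2 called 12 genes (9 higher, 3 lower), and limma on log2(FPKM + 1) called 0 with 1031 at unadjusted p below 0.05. Higher DESeq2 calls included Thap6, Rnase2b and Lhx1 at log2 fold changes of 23.9, 5.51 and 3.15. These are extreme estimates that edgeR did not call, singled out after their values were seen. The groups did not overlap for 498 genes (2.26%, chance 1.59%). The 10 genes with the smallest unadjusted p in edgeR, none of which passed there, were Gpt2, Klf9, Alkal2, Lefty1 and Gpd1 on the higher side and Plxdc2, Psmb9, Gcnt1, Etv6 and Sla on the lower. Of these, DESeq2 called Gpt2, Klf9, Plxdc2, Psmb9 and Gcnt1, each with an adjusted p of 0.0446. Gpt2, a mitochondrial alanine transaminase (ENSMUSG00000031700, chromosome 8, 86219205 to 86254189 in the table's coordinates), averaged 69.1 ± 1.63 CPM (SD, n = 4) in saline and 79.6 ± 2.80 CPM (SD, n = 5) in ACLP-NT. Klf9, a transcription factor induced by glucocorticoids, averaged 156 ± 8.93 and 183 ± 7.98 CPM. Without saline 32 the count was 1, the neuron navigator gene Nav2, which lies outside the naming rule and was singled out after its values were seen. The call of the inflammatory list ended without ACLP-NT 27 or without saline 32 (largest adjusted p 0.0985), that of heat shock genes without ACLP-NT 49 or saline 18, 19 or 32 (largest 0.407), and that of ribosomal proteins without ACLP-NT 27 or saline 32 or 38 (largest 0.348).

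**Figure D2:**
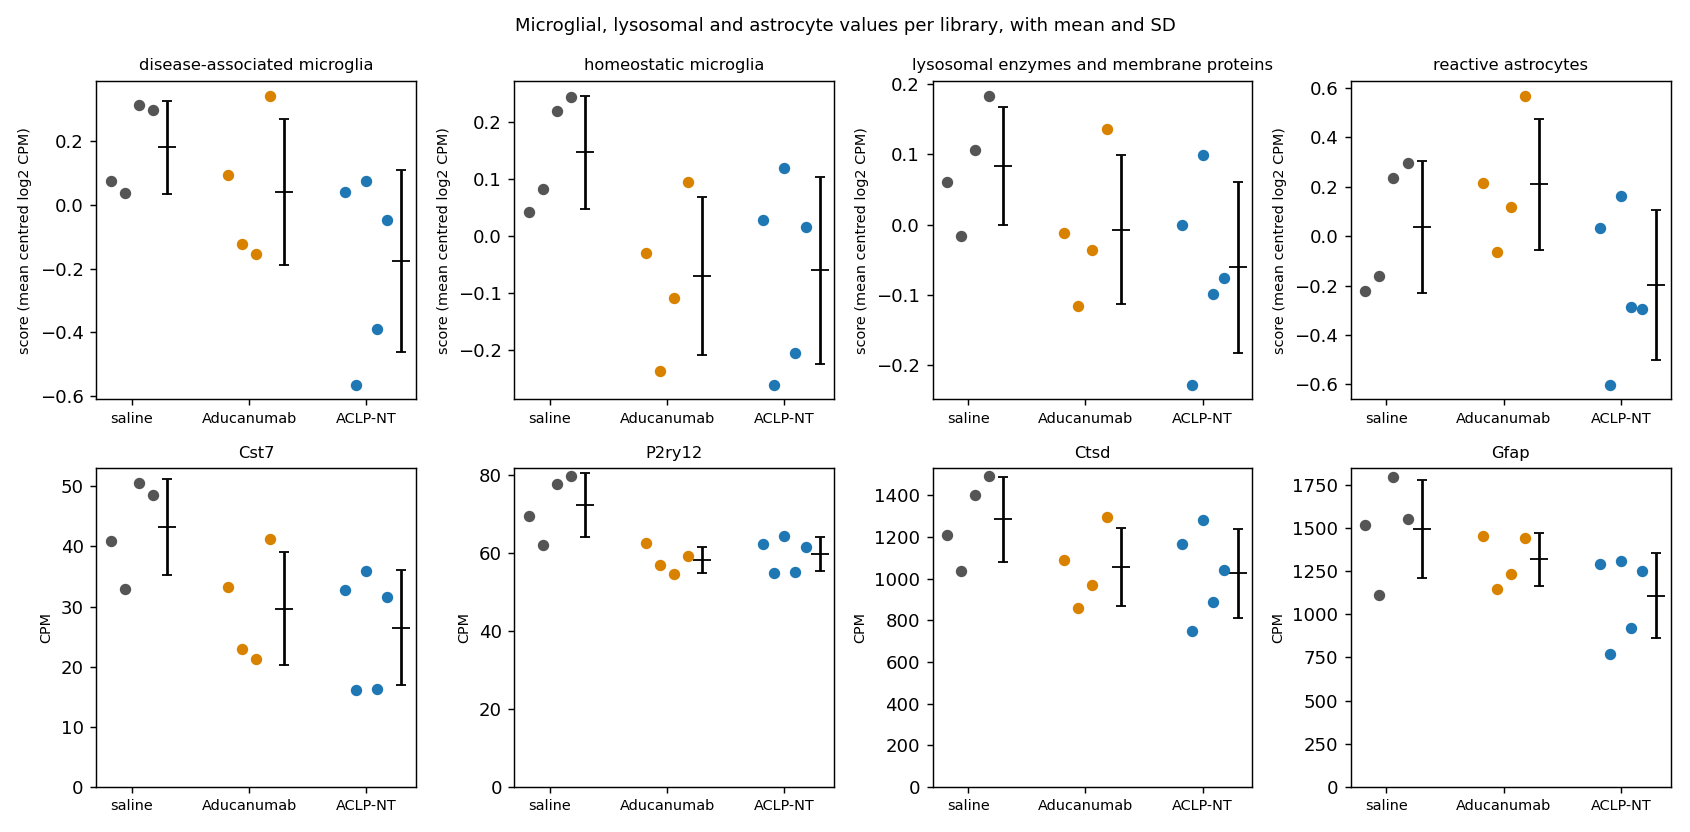
Scores of 4 lists (upper panels, mean centred log2 CPM) and levels of Cst7, P2ry12, Ctsd and Gfap (lower panels, CPM) per library in the 3 treatment groups, with the group mean and SD. On the disease-associated score ACLP-NT 27 and 53 are lowest, at -0.57 and -0.39, and ACLP-NT 17 and 49 lie within the saline range.

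Aducanumab against saline asks what the antibody changed. Homeostatic microglia transcripts were lower, with a median log2 fold change of -0.23 and 14 of 17 members below saline. P2ry12 averaged 58.2 ± 3.38 CPM (SD, n = 4) against 72.1 ± 8.16 CPM (SD, n = 4) in saline, and Sall1, a transcription factor of microglial identity, 31.8 ± 1.07 against 38.9 ± 1.64 CPM. Grn averaged 106 ± 11.6 CPM (SD, n = 4), a log2 fold change of -0.38 (SE 0.0908). Markers of the neocortex had a median of -0.35 (-0.23 without saline 19) with 10 of 12 lower, led by Tbr1, Cplx3 and Tshz2, whose log2 fold changes were -0.48 (SE 0.129), -1.63 (SE 0.460) and -1.27 (SE 0.380).

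Neither list was called with an estimated correlation. The homeostatic list had adjusted p = 0.532 with an estimated correlation, as had the neocortex list. Over all genes 0 members passed in edgeR, and 7 homeostatic members passed when adjusted over the list alone, all lower (Slc2a5, Sall1, P2ry12, P2ry13, Gpr34, Siglech and Cx3cr1). In the neocortex list Tbr1, Cplx3 and Tshz2 passed when adjusted over the list alone, and in the lysosomal list Grn did; DESeq2 called Grn over all genes (log2 fold change -0.39, adjusted p 0.0486). Markers of hippocampal subfields were not called (median 0.097, adjusted p 0.251), but when adjusted over the list alone Grik4, a kainate receptor subunit, passed with a log2 fold change of 0.36 (SE 0.106). Exact permutation of the homeostatic score gave p = 0.0857 for a difference of -0.22 (SE 0.0857), where the smallest p it allows is 0.0286.

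Other lists called with the preset correlation each had adjusted p = 0.824 with an estimated correlation. On the lower side were the lysosomal list (median -0.059, 36 of 50 lower), disease-associated microglia (-0.13, 22 of 27 lower), complement and phagocytic receptors (-0.22, 15 of 19), the interferon response (-0.22, 28 of 29), antigen presentation (-0.15, 16 of 19), cholesterol synthesis (-0.049, 16 of 20) and ribosomal proteins (-0.049, 29 of 32). Within the disease-associated list Cst7 was at -0.54 (SE 0.277), Clec7a at -0.51 (SE 0.225), Trem2 at -0.33 (SE 0.193) and Axl at -0.24 (SE 0.0893), while Spp1, which encodes osteopontin, was at 0.88 (SE 0.329) with 48.0 CPM in Aducanumab 58. Tissue markers were higher for the choroid plexus (median 0.82, all 18 members), thalamus and midbrain (0.37, 12 of 13, including Tnnt1, Vav3 and Prkcd) and blood cells (0.46, all 5, including Hba-a1 and Hbb-bs). Hemoglobin genes have close paralogs, which adds doubt to their single values. App and Tfeb were at 0.051 (SE 0.0514) and 0.0029 (SE 0.124), and Gfap, Ctsd and Lamp1 at -0.18 (SE 0.172), -0.29 (SE 0.166) and -0.075 (SE 0.0763). Several medians rested on single libraries. Without Aducanumab 58 the median was -0.11 for the lysosomal list, -0.24 for disease-associated microglia, -0.35 for interferon, -0.33 for antigen presentation, 0.020 for cholesterol synthesis, 0.28 for the choroid plexus and 0.11 for blood cells. Without Aducanumab 50 it was -0.15 for interferon, -0.041 for antigen presentation, -0.021 for cholesterol synthesis and -0.060 for thalamus and midbrain. Without saline 38 it was -0.087 for interferon, -0.031 for ribosomal proteins and 2.99 for the choroid plexus. Antigen presentation was at -0.25 and -0.058 without saline 18 and 19. Cholesterol synthesis was at -0.026 and -0.082 without saline 18 and 19, and at -0.13 and -0.092 without Aducanumab 24 and 56. The choroid plexus was at 0.43 and 0.46 without saline 18 and 32, and at 0.47 without Aducanumab 56.

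The 22 remaining lists had adjusted p from 0.0541, for meningeal fibroblasts with a median of 0.37, to 0.971. The median was 0.071 for reactive astrocytes, -0.0047 for amyloid processing, 0.014 for V-ATPase subunits and -0.017 for autophagy. Median, mean and test did not share a sign for V-ATPase subunits, astrocyte markers, synaptic genes, neurogenesis, lipid handling, the oxidative stress response and amyloid processing.

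In edgeR 0 of 22065 genes passed, with the smallest adjusted p at 0.485. At an unadjusted p below 0.05 there were 1033 genes, 456 higher and 577 lower, where 5% of the genes tested is 1103 and the median over 35 splits, the real one included, was 1033; DESeq2 called 19 (11 higher, 8 lower), and limma on log2(FPKM + 1) called 0 with 731 at unadjusted p below 0.05. The groups did not overlap for 569 genes (2.58%, chance 2.86%). The 10 genes with the smallest unadjusted p in edgeR, none of which passed there, were Ccdc96, Col25a1, Gpd1, Plekhf1, B4galt4, Gpt2 and Myo5b on the higher side and Efhd2, Ikzf1 and Hhex on the lower. DESeq2 called all of them but Gpt2, with adjusted p from 0.00278 to 0.0486. Col25a1, a collagen whose fragment binds amyloid plaques, averaged 61.7 ± 4.79 CPM (SD, n = 4) in saline and 80.4 ± 4.01 CPM (SD, n = 4) in Aducanumab. Ikzf1, a transcription factor of blood-lineage cells, averaged 12.6 ± 1.13 and 8.51 ± 0.864 CPM. The count was 1 without saline 32 (Nav2) and 1 without ACLP-NT 49 (4933407K13Rik), both outside the naming rule and singled out after their values were seen. Without Aducanumab 50, 5 lists were called in place of 12: the calls of disease-associated microglia, the lysosomal list, complement, interferon, antigen presentation, cholesterol synthesis, blood cells and thalamus ended, with the thalamus median at -0.060, and reactive astrocytes were called higher (median 0.15). Calls also ended without saline 32 or Aducanumab 56 for disease-associated microglia (largest adjusted p 0.0769), without saline 19 for antigen presentation, without saline 18, saline 32, Aducanumab 56 or 58 for the choroid plexus (largest 0.176), without saline 38 or Aducanumab 56 for ribosomal proteins (largest 0.257), without saline 18, saline 38 or Aducanumab 58 for blood cells (largest 0.562) and without saline 18, saline 32 or Aducanumab 58 for cholesterol synthesis (largest 0.659).

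ACLP-NT against Aducanumab compares the treatments directly. Reactive astrocyte transcripts were lower in ACLP-NT, with a median log2 fold change of -0.29 and all 21 members below Aducanumab. That median was -0.13 without Aducanumab 58 and -0.18 without ACLP-NT 27, the libraries with the highest and lowest scores for this list (0.57 and -0.60). Gfap averaged 1319 ± 154 CPM (SD, n = 4) in Aducanumab and 1108 ± 247 CPM (SD, n = 5) in ACLP-NT, and Ggta1, a galactosyltransferase of that state, 14.3 ± 2.37 and 9.95 ± 2.38 CPM. Disease-associated microglia transcripts had a median of -0.16 with 24 of 27 lower; Spp1, Cybb and Itgax led that list, and Spp1 averaged 26.7 ± 14.9 against 12.2 ± 4.50 CPM. The median of the list was -0.073 without Aducanumab 58, -0.052 without ACLP-NT 27 and -0.090 without ACLP-NT 53. Hippocampal subfield markers were higher in ACLP-NT with a median of 0.12, including Wfs1, a marker of CA1 neurons, at 97.8 ± 15.2 against 71.1 ± 7.94 CPM; that median was 0.055 without Aducanumab 24, 0.036 without Aducanumab 50 and 0.044 without ACLP-NT 53. Homeostatic microglia did not differ detectably, with a median of 0.00037 and a score difference of 0.010 (SE 0.101).

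With an estimated correlation no list was called. Reactive astrocytes and hippocampal subfields each had adjusted p = 0.528 with an estimated correlation. Over all genes 0 reactive astrocyte members passed in edgeR, and Timp1, Lcn2 and Ggta1 passed when adjusted over the list alone; Lcn2 and Timp1 were near the floor, at 0.721 and 1.07 CPM in Aducanumab. Exact permutation gave p = 0.0794 for reactive astrocytes (score difference -0.41, SE 0.190) and p = 0.0159 for hippocampal subfields (0.19, SE 0.0287), which was 0.540 after adjustment over the 34 lists. Here too the smallest p the permutation test allows is 0.00794, so 1 list alone could not pass after adjustment.

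Among other calls, immediate early genes (Arc, Nr4a1 and Egr3) had a median of 0.13 and blood cells of -0.60 (all 5 lower), each with adjusted p = 0.795 with an estimated correlation. The remaining ones had adjusted p = 0.910 with an estimated correlation: disease-associated microglia, meningeal fibroblasts (median -0.44, including Col3a1, Mgp and Fmod), thalamus and midbrain (-0.36, including Synpo2, Tnnt1 and Tcf7l2), complement (-0.11, including Cd14 and C4b), antigen presentation (-0.15, including Cd74 and H2-Ab1), the lysosomal list (-0.051, 41 of 50 lower), oligodendrocytes and myelin (-0.084) and mitochondrially encoded genes (-0.065, all 13 lower). Of the members the rule also names, Scarb1 of the complement list and Tmem175 of the lysosomal list leaned higher in ACLP-NT. Scarb1 ran from 31.3 to 35.2 CPM in ACLP-NT and from 30.1 to 33.2 CPM in Aducanumab. For Tmem175 the ranges were 51.1 to 53.7 and 49.0 to 52.5 CPM. Counts of mt-Atp6, mt-Co2 and mt-Co3 stand beside near-equal counts of nuclear copies (Atp6-ps, Gm28661 and Gm28437), so the levels of these mitochondrial genes are uncertain. Over the 13 libraries the blood and meningeal scores were highest in Aducanumab 58 (1.12 and 1.41) and the thalamus score in Aducanumab 50 (1.3). Without Aducanumab 58 the median was 0.066 for immediate early genes, -0.23 for blood cells, 0.050 for meningeal fibroblasts, -0.026 for complement, 0.0064 for antigen presentation, -0.0029 for the lysosomal list, -0.034 for oligodendrocytes and -0.019 for mitochondrially encoded genes. Without Aducanumab 50 it was 0.082 for immediate early genes, -0.66 for meningeal fibroblasts, 0.038 for thalamus, -0.19 for complement and -0.081 for the lysosomal list. Without ACLP-NT 27 it was -0.024 for complement, -0.069 for antigen presentation, -0.0061 for the lysosomal list and 0.0072 for oligodendrocytes. Without ACLP-NT 49 it was -0.73 for thalamus, -0.20 for complement, -0.090 for the lysosomal list, -0.14 for oligodendrocytes and -0.034 for mitochondrially encoded genes. Without ACLP-NT 53 it was -0.66 for meningeal fibroblasts, -0.060 for complement and -0.17 for oligodendrocytes, and without ACLP-NT 55 it was -0.26, -0.22, -0.085 and -0.14 for meningeal fibroblasts, thalamus, antigen presentation and oligodendrocytes. Oligodendrocytes were at 0.013 without ACLP-NT 17 and -0.18 without Aducanumab 24. Thalamus was at -0.65 and -0.59 without Aducanumab 24 and 56, and meningeal fibroblasts at -0.67 without Aducanumab 56. The other 22 lists had adjusted p from 0.0671 to 0.997, with medians of -0.0035 for V-ATPase subunits, 0.0096 for autophagy, 0.00017 for amyloid processing and -0.085 for the choroid plexus. Median, mean and test did not share a sign for synaptic genes, amyloid processing, the choroid plexus and lymphocytes. Of the genes named in every comparison, Cst7, Trem2 and Clec7a were at -0.16 (SE 0.262), -0.18 (SE 0.183) and -0.12 (SE 0.214). P2ry12 and App were at 0.034 (SE 0.0754) and -0.029 (SE 0.0487), and Ctsd, Lamp1 and Tfeb at -0.040 (SE 0.158), -0.048 (SE 0.0723) and -0.085 (SE 0.118).

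In edgeR 0 of 22065 genes passed and every adjusted p was 1. At an unadjusted p below 0.05 there were 716 genes, 338 higher and 378 lower, where 5% of the genes tested is 1103 and the median over 100 splits, the real one included, was 875; DESeq2 called 3 (Gh, 4933407K13Rik and Rnasek, the first and second singled out after their values were seen), and limma on log2(FPKM + 1) called 0 with 501 at unadjusted p below 0.05. Gh had a DESeq2 log2 fold change of -7.98 (SE 1.43), an extreme estimate that edgeR did not call. The groups did not overlap for 295 genes (1.34%, chance 1.59%). The 10 genes with the smallest unadjusted p in edgeR, none of which passed there, were Htr1f, Suv39h2, Cwh43 and Cadm2 on the higher side and Rnasek, Smoc1, Col25a1, Xrcc5, Aldh1a3 and Slc10a5 on the lower, and of these DESeq2 called Rnasek (adjusted p 0.0235). Rnasek averaged 28.2 ± 9.38 CPM (SD, n = 4) in Aducanumab and 15.9 ± 1.88 CPM (SD, n = 5) in ACLP-NT, and Smoc1, a secreted matrix protein, 20.9 ± 3.47 and 13.6 ± 1.38 CPM. For Rnasek, Aducanumab 24 and 58 stood at 38.7 and 33.6 CPM and Aducanumab 50 and 56 at 20.2 and 20.4 CPM. Saline libraries ran from 14.1 to 18.2 CPM, so ACLP-NT lay near the saline level. DESeq2 also called Rnasek higher in Aducanumab against saline (log2 fold change 0.77, adjusted p 0.0437). Without ACLP-NT 49 the count was 1 (4933407K13Rik). Without Aducanumab 58, calls ended for the lysosomal list, complement, antigen presentation, immediate early genes, blood cells, meningeal fibroblasts (median 0.050), mitochondrially encoded genes and oligodendrocytes, and without Aducanumab 50 for thalamus (median 0.038) and oligodendrocytes. Calls also ended without Aducanumab 24 or ACLP-NT 27 or 53 for complement (largest adjusted p 0.394), without ACLP-NT 27 or 55 for antigen presentation, without ACLP-NT 27, 53 or 55 for the lysosomal list (largest 0.860), without ACLP-NT 55 for meningeal fibroblasts, without Aducanumab 24 or ACLP-NT 49 or 55 for mitochondrially encoded genes (largest 0.428) and without ACLP-NT 17 or 27 for oligodendrocytes (largest 0.935).

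**Figure D3:**
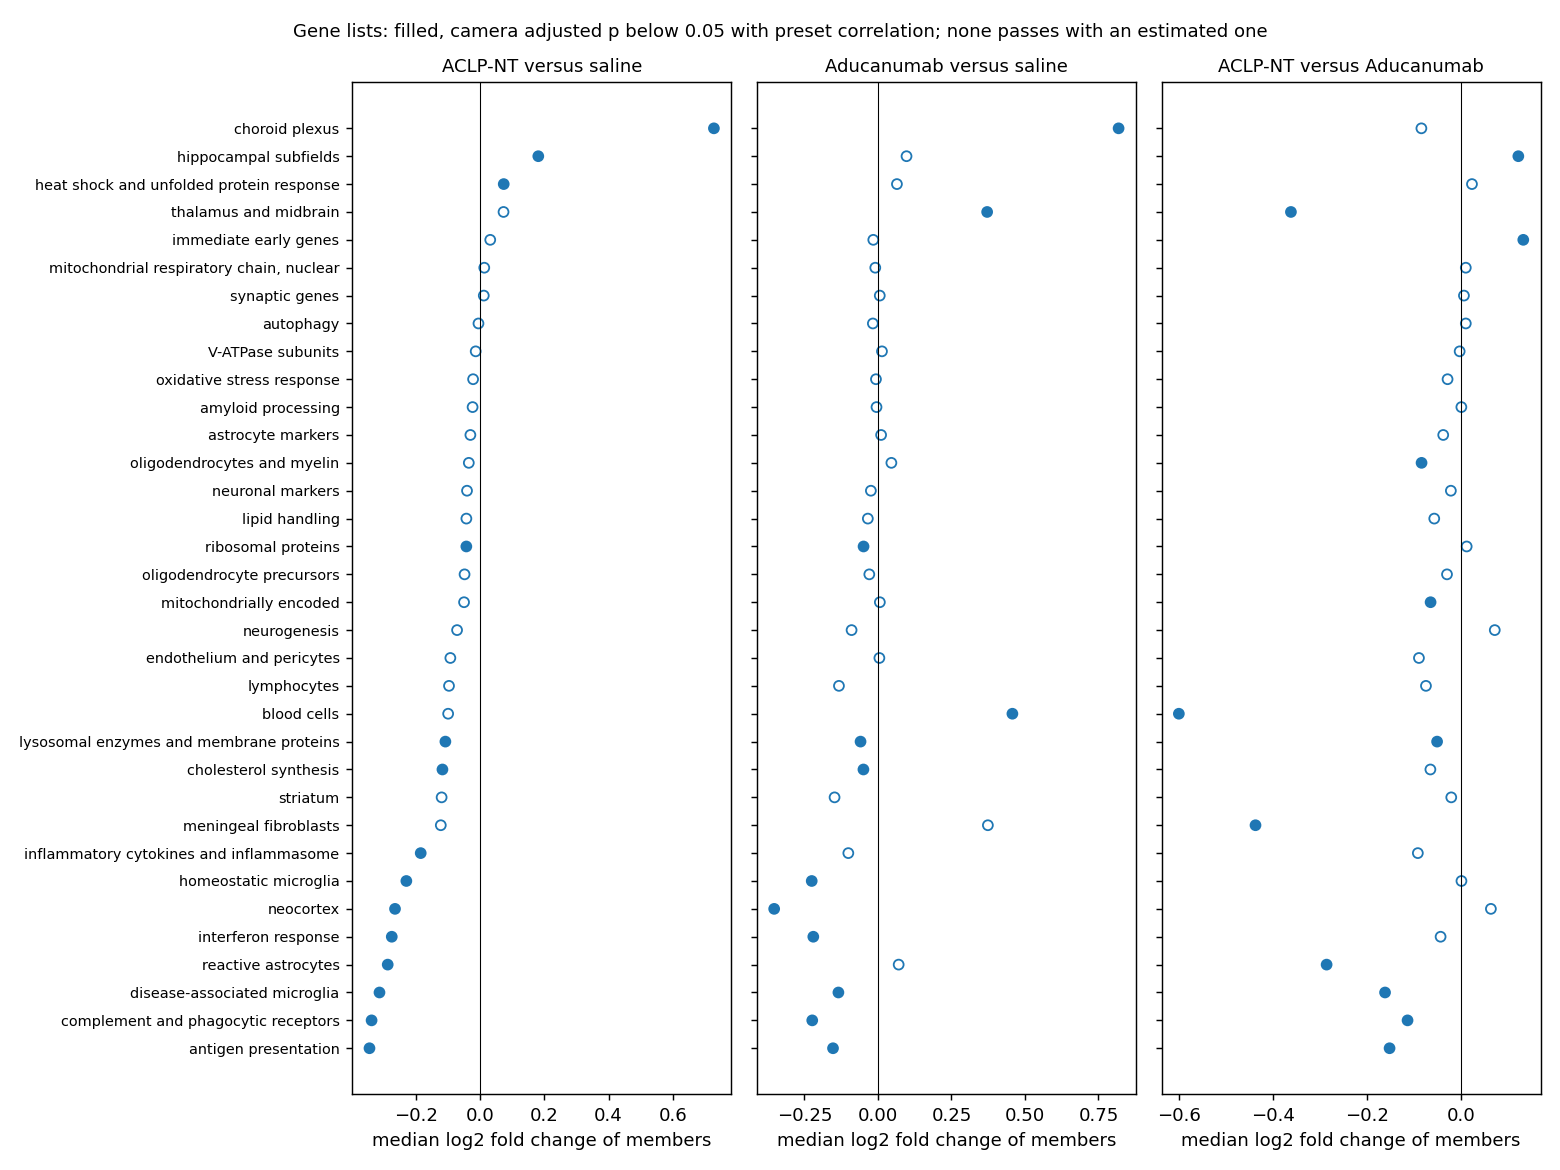
Median log2 fold change of each gene list (horizontal axes, a separate scale per panel) in the 3 comparisons, with filled points for lists called by camera with the preset correlation. In ACLP-NT against saline 14 lists are called, 11 lower and 3 higher, and 0 are called with an estimated correlation.

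**Figure D4:**
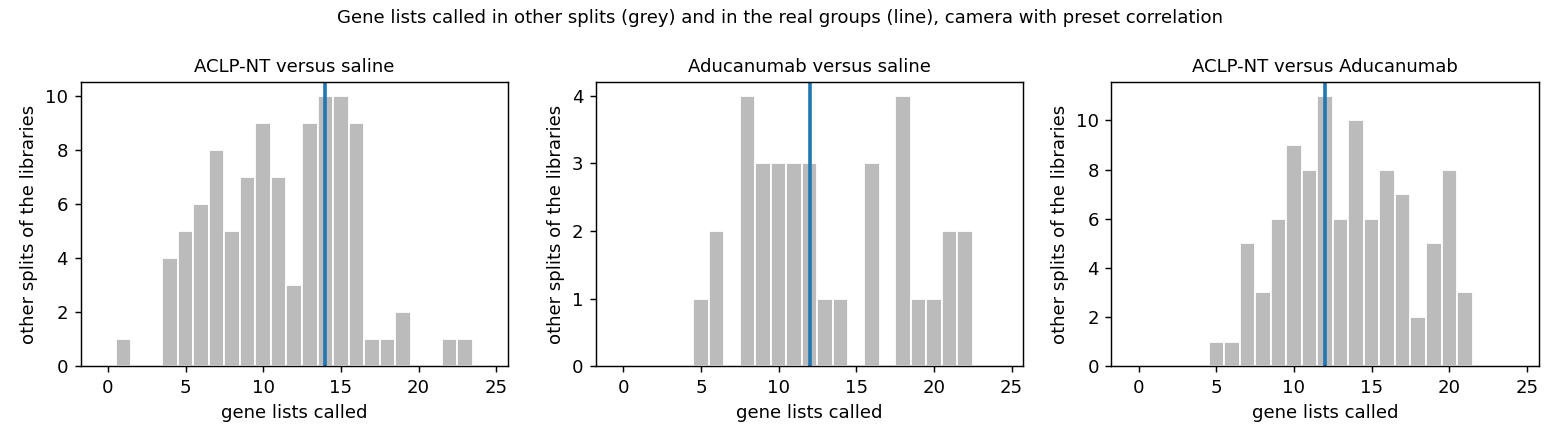
Number of lists that camera with the preset correlation calls (horizontal axes) over other splits of the same libraries (grey bars, number of splits), with the real groups as a line. The real counts of 14, 12 and 12 lists lie within the ranges of the other splits, which reach 23, 22 and 21.

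Fold changes of both treatments against saline are not independent, since the saline libraries are shared. Across genes, which are not independent replicates, the 2 sets of differences in mean log2 CPM had a correlation of 0.570. In 20 simulations of unchanged groups set against shared controls the correlation was 0.50 to 0.54, and the covariance was 0.0762 against 0.0559 to 0.0627. At unadjusted p below 0.05, 203 genes were lower and 172 higher in both treatments, against 99.0 (84 to 120) and 139 (117 to 160) in the simulations. Each gene was simulated independently, so these ranges are too narrow for genes that vary together. Values beyond them therefore do not show an effect shared by the treatments. With each treatment set against a separate pair of saline libraries, over 6 splits, the correlation was -0.0092 to 0.10 and the covariance -0.0019 to 0.019. In edgeR 0 genes passed in both.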

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

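The tests of choroid plexus carry-over, fewer microglia and treatment, the counts of splits for genes and for single lists, and the tissue scores of splits were chosen only after the result was seen; the test on lysosomal members and the counts of splits for lists were not. A first test of the microglial pattern on neuronal markers was replaced by the one with a choroid plexus covariate, and the bound for a treatment effect on the choroid plexus was narrowed, each after a first result was seen.

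Microglial lists lay lower in ACLP-NT than in saline. Carry-over of choroid plexus as the whole source is argued against by the fit with the choroid plexus score as a covariate. The median of the disease-associated list was -0.34 there. Lists newly called in that fit with the preset correlation were meningeal fibroblasts (-0.40), endothelium and pericytes (-0.15), mitochondrially encoded genes (-0.062) and synaptic genes (0.040). The neuronal marker score differed by -0.048 (SE 0.0548, exact permutation p 0.421). That value cannot decide on carry-over, as its spread leaves room for dilution and neighbouring brain regions hold neurons too. Fewer microglia and a shift in their state cannot be told apart: the ACLP-NT minus saline difference was larger for the disease-associated than for the homeostatic score, by -0.15 (SE 0.0643), with an exact permutation p of 0.0556. A treatment effect stays open with an exact permutation p of 0.0794. Among 100 splits of these libraries, the real one included, 9 gave a disease-associated median as far from 0 (real -0.31, highest other 0.37) and 12 a homeostatic one (real -0.23, highest other 0.27), so chance cannot be excluded.

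The lysosomal list lay lower in ACLP-NT than in saline. It holds 10 members known to be enriched in microglia (among them Ctss, Cd68 and Grn), whose median was -0.35 with 10 of 10 lower (exact permutation p 0.0714). The other 40 had a median of -0.079 with 31 lower (exact permutation p 0.103), between the bounds set beforehand, so a lower share of microglial transcripts and a change in lysosomal genes of other cells cannot be told apart. In 15 of 100 splits, the real one included, the median of the list was as far from 0 (real -0.11, highest other -0.18), and chance cannot be excluded.

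Choroid plexus markers differed between libraries more than any other list. Varying carry-over of that tissue is in line with a median correlation of 0.988 between a member and the mean of the others within groups (lowest 0.946), as 1 source would keep its genes in 1 ratio. A treatment effect on the choroid plexus stays open, with 0.294 as the smaller exact permutation p of both comparisons with saline. Dissection records, which would decide it, are not used here.

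The counts of genes and lists were set beside 100, 35 and 100 splits of the same libraries in ACLP-NT against saline, Aducanumab against saline and ACLP-NT against Aducanumab, and each number of splits includes the real one. No split can give fewer genes than the real 0 of edgeR, so the splits say nothing on that count; the highest of the others was 1, 1 and 9. At an unadjusted p below 0.05, 18 of 100 splits gave as many genes as the real 1298 (highest other 1931), 18 of 35 as many as 1033 (highest other 2403) and 76 of 100 as many as 716 (highest other 2676), so chance cannot be excluded. The splits with these highest counts parted libraries with high and low choroid plexus scores: the means of the sides were 1.74 and -1.62, 1.42 and -2.10, and 2.02 and -0.84, and 2 of 100, 2 of 35 and 2 of 100 splits were as far apart on that score. For lists called with the preset correlation, 36 of 100 splits gave as many as the real 14 (highest other 23), 19 of 35 as many as 12 (highest other 22) and 67 of 100 as many as 12 (highest other 21). The median over splits was 11, 12 and 13 lists, so this test calls about as many lists for arbitrary groups of these libraries, and chance cannot be excluded for any of the 3 counts. The homeostatic median in Aducanumab against saline (real -0.23, highest other -0.26) was matched or exceeded in 3 of 35 splits and the reactive astrocyte median in ACLP-NT against Aducanumab (real -0.29, highest other -0.47) in 18 of 100, so chance cannot be excluded there either.

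Single libraries lay far from the rest of their group by Dixon's test for 12 of 108 scores and library measures and for 24 of 369 gene levels, where chance gives 5.40 and 18.4. Among scores, Aducanumab 58 was apart for V-ATPase subunits (-0.088), oligodendrocyte precursors (0.19), the oxidative stress response (0.16) and heat shock genes (0.15). ACLP-NT 53 was apart for neuronal markers (-0.15), cholesterol synthesis (-0.26), total count (53642019) and genes detected (26556). ACLP-NT 55 was apart for endothelium and pericytes (-0.33) and meningeal fibroblasts (-1.27), and ACLP-NT 49 for autophagy (0.049) and hippocampal subfields (0.015). Among gene levels in CPM, Aducanumab 58 was apart for Gpd1 (113), Lgmn (145), Gbp2 (12.6), Lamp1 (383), Neu1 (51.6), Nr4a1 (41.8) and Col3a1 (14.0), and Aducanumab 50 for Ifi204 (2.31), Tnnt1 (7.86) and Tcf7l2 (28.3). Saline 38 was apart for Gcnt1 (9.76) and for the choroid plexus genes Otx2 (21.1), Kl (228), Prlr (72.2) and Col8a1 (30.1), and saline 19 for Col25a1 (68.8). In ACLP-NT, library 53 was apart for Gpd1 (125), library 49 for Gbp2 (10.4), Hspa8 (1752) and Prkcd (53.4), library 17 for Mvd (20.1), and library 55 for Slc10a5 (0.0616), Mgp (3.96) and Fmod (3.76).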

How the results depend on the processing

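Fits with covariates and the fit without 3 libraries were chosen only after the result was seen. No paired analysis was possible because no replicate number is shared between groups. Of 4424 fold changes of named genes over 29 alternatives, 4381 kept their sign, and no scaling moved the median of all genes by over 0.1. Many of these genes were named for a small p in the same libraries. Kept signs are therefore largely given by that choice and are no independent support. With an estimated correlation and with fry, 0 lists were called in each comparison, where the first changes the correlation alone and fry tests a list against no change, not against other genes; the medians stay those reported. They are -0.31 for disease-associated microglia, -0.23 for homeostatic microglia and -0.11 for lysosomal genes in ACLP-NT against saline, with adjusted p over all camera alternatives of 5.34e-20 to 0.336, 1.56e-12 to 0.336 and 3.82e-17 to 0.402 (with fry 0.352, 0.352 and 0.430). In Aducanumab against saline they are -0.13, -0.23 and -0.059 (4.68e-07 to 0.824, 4.24e-15 to 0.532 and 2.24e-09 to 0.824, and with fry 0.872, 0.701 and 0.872), and in ACLP-NT against Aducanumab -0.16 and -0.051 for disease-associated and lysosomal genes (3.54e-08 to 0.910 and 3.38e-05 to 0.997, and with fry 0.925 for both). For the other lists called, the largest adjusted p of any camera alternative was 0.176 to 0.999, and that of fry 0.236 to 0.925.

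For genes, DESeq2 called 12, 19 and 3 in the order above. In Aducanumab against saline limma called 1 (Snord32a, singled out after its values were seen) with quantile normalization and 1 with array weights, where edgeR called 0; the cause was not tested. Leaving out 1 library gave 0 to 1 gene in each comparison. Lists called in Aducanumab against saline were 7 with a mean FPKM of at least 5, where fewer genes and lists are tested, and in ACLP-NT against Aducanumab 5 with array weights; the cause was not tested. With array weights and without 3 libraries the lysosomal median in the latter was -0.033 and -0.029, no longer past the threshold. Cholesterol synthesis, not called in ACLP-NT against Aducanumab by the main fit, was called lower there in every limma fit, with the preset correlation. Its medians were -0.052 and -0.055 with log2(FPKM + 1) and log2(FPKM + 0.1), -0.050 with quantile normalization and -0.075 with array weights. It was also called lower with a mean FPKM of at least 5 (-0.059) and without Aducanumab 50 (-0.092), Aducanumab 58 (-0.13) or ACLP-NT 17 (-0.073).

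Leaving out 1 library gave 13 to 18, 5 to 15 and 8 to 18 lists. In Aducanumab against saline the disease-associated median then ran from -0.24 to -0.096 and the lysosomal one from -0.11 to -0.047, and in ACLP-NT against Aducanumab from -0.24 to -0.052 and from -0.090 to -0.0029. The lysosomal median in ACLP-NT against saline ran from -0.13 to -0.066. Of the lists called with all libraries, some medians changed sign at one end. Thalamus did in both comparisons with Aducanumab (-0.060 to 0.49 against saline, -0.73 to 0.038 for ACLP-NT against it). Cholesterol synthesis did in Aducanumab against saline (-0.13 to 0.020). In ACLP-NT against Aducanumab, antigen presentation (-0.22 to 0.0064), meningeal fibroblasts (-0.67 to 0.050) and oligodendrocytes (-0.18 to 0.013) did. Calls with the preset correlation also appeared in alternatives. Meningeal fibroblasts in Aducanumab against saline were called higher without saline 19 (0.43) or 38 (0.66) or Aducanumab 24 (0.48) or 56 (0.64), among others. Immediate early genes in ACLP-NT against saline were called higher with a mean FPKM of at least 5 (0.13) and without saline 32 (0.056) or ACLP-NT 49 (0.067), among others.

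Without saline 38, Aducanumab 50 and Aducanumab 58, some medians of lists called with all libraries turned. In Aducanumab against saline these were cholesterol synthesis (0.071), blood cells (-0.25) and thalamus (-0.17). In ACLP-NT against Aducanumab they were oligodendrocytes (0.052), meningeal fibroblasts (0.12), blood cells (0.039) and thalamus (0.29). Newly called in the latter were cholesterol synthesis (-0.20), synaptic genes (-0.071) and V-ATPase subunits (-0.049) as lower. Endothelium and pericytes (0.090) and neocortex (0.28) were newly called there as higher. The libraries left out include those with the highest blood, meningeal and thalamus scores. Other alternatives called endothelium and pericytes lower in ACLP-NT against Aducanumab. These included fits without Aducanumab 24 (-0.12), 50 (-0.10) or 56 (-0.15) and a mean FPKM of at least 5 (-0.13). Synaptic genes were called higher without Aducanumab 24 (0.039), 50 (0.014) or 56 (0.041) and lower without Aducanumab 58 (-0.048). The direction of these calls thus depended on the fit. With choroid plexus and thalamus scores as covariates, cholesterol synthesis in Aducanumab against saline was at 0.0087 and the choroid plexus list in ACLP-NT against saline at -0.0037, which the covariate removes by construction. Depth limits weakly expressed genes: at their mean counts in Aducanumab, counting error alone in 1 library is 15.3% of the level for Lcn2 and 12.5% for Timp1.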

Other observations

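The tests on KEGG pathways and on relations between scores were chosen only after the result was seen. Among 321 KEGG pathways of the table's annotation, camera with the preset correlation called 29 lower and 0 higher in ACLP-NT against saline, including Lysosome (median -0.037, 126 genes), Phagosome (-0.060, 142 genes) and Complement and coagulation cascades (-0.17, 60 genes). In Aducanumab against saline 2 were called lower, among them Ribosome (-0.040), and 3 were called lower in ACLP-NT against Aducanumab. With an estimated correlation 0 were called, with the smallest adjusted p at 0.813, 0.972 and 0.981. Igkc, an immunoglobulin light chain gene, stood at 12.9 CPM in ACLP-NT 53 and at 0 to 1.2 CPM in the other libraries.

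Disease-associated microglia and reactive astrocyte scores may vary together between animals whatever the treatment. Within groups, over 13 libraries, Pearson's r was 0.897 and Spearman's rho 0.786 (permutation p 0.000460 and 0.00619; adjusted over 8 relations 0.00123 and 0.00990), and r was 0.888 without the 2 libraries farthest from the median, with 0 members shared. Against the disease-associated score, r was 0.954 for homeostatic microglia, 0.896 for the lysosomal list, 0.869 for the interferon response and 0.852 for complement, with rho of 0.907, 0.907, 0.830 and 0.879 (adjusted permutation p of r 0.000960, 0.000960, 0.00282 and 0.00282). For synaptic genes r was -0.51 and rho -0.55 (adjusted permutation p 0.123 and 0.0821), for amyloid processing 0.211 and 0.236 (0.612 and 0.550) and for the choroid plexus 0.131 and 0.126 (0.680 and 0.692).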
